A study of Mus musculus with 10 samples.

How the data were processed

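Messenger RNA levels were measured with Affymetrix 3' expression arrays in mouse embryonic fibroblasts, on 10 arrays in 5 groups of 2. Per the labels, total RNA was extracted with Trizol and RNeasy columns, and biotin-labelled RNA for hybridisation was made in one round of reverse transcription and in vitro transcription. The deposited values are signal intensities on a linear scale, made by the authors with the Affymetrix software GCOS 1.4, per the submitters' processing notes. The trimmed mean signal, leaving out 2% of probe sets at each end, lay at about 500.1 on every array, so the deposited values had already been brought to 1 level, and they were used without further scaling. Which background correction and scaling options were chosen in that software is not given in the sources used here. For arrays, the number of arrays in a group, here 2, limits the precision.

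Groups were taken from the sample titles and the design text: fibroblasts without G9a that received an empty vector (delta), FLAG-tagged wild-type G9a (WT), FLAG-G9a with the K165A substitution (K165A) or the catalytic mutant H1093K (H1093K), and a pair of arrays titled only as deleted. What vector, if any, the cells of that last pair carried is not given in the sources used here, so they are called the arrays labelled deleted. The design text speaks of independent analyses in duplicate, but nothing says that arrays of a group came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical.

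The table held 22690 probe sets, of which 64 were controls and were left out of the tests. Of the other 22626, the platform annotation named 20380 by 1 gene, 691 by several and 1555 by none, with symbols updated through the mouse reference gene table of GRCm38.p6, from which no coordinates were used. Probe sets named by several genes or by none were tested and counted but never named. No genome build is given in the sources used here, and no positions are reported.

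Signals were analysed as log2(signal + 16). Probe sets whose mean over the 10 arrays lay under the 40th percentile were left out, which kept 13575, of which 12526 had 1 gene; these covered 7741 genes. In R 4.3.3, limma 3.58.1 (lmFit, then eBayes with an intensity trend) was fitted to all 10 arrays with 1 mean per group. The fit had 5 residual degrees of freedom, to which the prior added 4.73. The 7 comparisons were tested, each against a Benjamini-Hochberg adjusted p of 0.05 over the 13575 probe sets. Fold changes are on the log2(signal + 16) scale and so understate the change of dim probe sets. No fold is given for a named gene whose mean in one of the groups compared lay under the pseudocount of 16. Where a comparison of 1 gene is made from 2 arrays against 2, an exact two-sided permutation test cannot give a p below 0.333, so no such test is reported.

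Named genes followed a fixed rule. For each comparison it took up to 10 genes with the largest rise and up to 10 with the largest fall among probe sets with 1 gene that passed the threshold and whose 2 arrays of one group both lay beyond the 2 arrays of the other. A gene with several probe sets was taken by the one of highest mean. Where fewer than 10 passed, the 10 genes of smallest p were taken. Ehmt2 and Ehmt1 were added in every array, and up to 4 members of smallest p for each gene list. Ehmt1 had no probe set of its own under this annotation and is not analysed here.

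There were 21 gene lists, fixed from general knowledge: H3K9 methylation machinery, imprinted genes, germline and pluripotency genes, interferon-stimulated genes, cell cycle genes, p53 targets and cell cycle inhibitors, extracellular matrix genes, smooth muscle and contractile genes, adipocyte and lipid genes, bone and cartilage genes, skeletal muscle genes, Hox genes with their cofactors, neuronal genes, markers of macrophages and leukocytes, of endothelium and of epithelium, unfolded protein and amino acid stress genes, hypoxia and glycolysis genes, cholesterol synthesis genes, immediate early genes, and inflammatory and NF-kB genes. Lists with at least 5 measured genes were tested with camera from limma, 1 probe set per gene, with the preset inter-gene correlation of 0.01. Adjustment ran over all 133 pairs of list and comparison. With an estimated correlation in place of the preset one, 0 of the 48 pairs that passed kept an adjusted p under 0.05. In 18 of the 133 pairs, of which 0 passed, the median, the mean and the camera direction did not all share a sign. Germline and pluripotency genes had 2 measured members and skeletal muscle genes 1, so they were not tested. Counts of members that rose or fell come from limma, adjusted over all probe sets, and are also given adjusted over the list alone.

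How far each mutant followed the WT response was measured as the slope, through the origin, of its log2 differences from delta on those of WT, over the probe sets past the threshold in WT against delta. Both differences use the same delta arrays. The slope, shared sign and covariance that this sharing gives were therefore taken from 100 simulated data sets in which the mutant equalled delta. Their noise was drawn independently for each probe set and array. It left out correlation between genes and between same-numbered arrays.

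In every group, the title of 1 array ends in _2 and the other title carries no number. The array without a number is called replicate 1 here. Deviations from the group means were positively correlated between arrays of the same number in all 10 pairs of groups (0.234 to 0.527 across probe sets), so same-numbered arrays were taken as paired. The basis is this check and the duplicate analyses of the design text; the labels name no shared day or batch. The fit without the block is the main one, and the fit with the replicate number as a block is given where it changed a call or moved a count by more than 1.5 times.

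The groups, the tests, the gene lists, the rule for named genes and all but 2 of the alternative settings were chosen before the data were examined. The alternatives were other pseudocounts (1 and 64), no filter and a filter at the 60th percentile, quantile normalisation, median centring and cyclic loess, no intensity trend, array weights, only the arrays of the groups compared, a minimum fold of 1.5, the replicate block, another control group, an estimated correlation, a gene taken as the mean of its probe sets, a fixed set of 200 probe sets for the slope, and each array left out in turn. Leaving out the arrays labelled deleted, and a slope of mutant minus deleted on WT minus delta, were added after seeing the data; the second is another reading of the planned slope against the arrays labelled deleted, and both readings were run.

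The procedure was tested on simulated data built on the 13575 probe sets of WT against delta. It recovered 56.7% of probe sets changed 1.5-fold, 92.0% of those changed 2-fold and 99.7% of those changed 4-fold, and 5.86% of its calls were false. A simulated slope of 0.5 was found as 0.504. With no change simulated, 3.31% of camera tests gave a p under 0.05, and a list shifted by 0.3 (log2) was called in 100% of 10 runs. The simulated noise was drawn independently for each probe set and array. All of these rates therefore leave out correlation between genes and between same-numbered arrays, and cannot show how the procedure fares with it. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.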

Results

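Expression was measured in mouse embryonic fibroblasts, connective tissue cells grown from mouse embryos, on 10 Affymetrix arrays. G9a, encoded by Ehmt2, is an enzyme that methylates lysine residues of histone H3 and of other proteins, itself included. The cells of 4 groups had lost G9a and were given an empty vector (delta), FLAG-tagged wild-type G9a (WT), FLAG-G9a with the K165A substitution, or FLAG-G9a with the H1093K substitution, which the labels call a catalytic mutant. The last group is titled only as deleted. Each group had 2 arrays. The series title concerns methylation of G9a at a site that resembles histone, and the comparisons show how expression changed when wild-type G9a was restored and whether either substitution altered that change. The median signal lay between 181 and 199 on the 10 arrays. The 2 arrays of a group correlated with Pearson's r of 0.984 to 0.989 across probe sets, which are not independent replicates. Across the 5 groups, limma found a difference in 4915 of 13575 probe sets tested (36.2%), and across the 4 groups without the arrays labelled deleted in 1289 (9.50%). The first count was 3265 without deleted replicate 1.

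By the probe set tested, Ehmt2 itself was higher where wild-type or K165A G9a had been added, near the delta level in the H1093K arrays, and highest in the arrays labelled deleted. Its signal was 444 ± 41.0 (SD, n = 2) in delta, 648 ± 39.4 (SD, n = 2) in WT, 714 ± 14.5 (SD, n = 2) in K165A, 478 ± 23.8 (SD, n = 2) in H1093K and 1714 ± 50.9 (SD, n = 2) in the arrays labelled deleted. Against delta, the log2 difference was 0.53 in WT (95% interval 0.33 to 0.74, limma adjusted p = 0.00474) and 0.67 in K165A (0.47 to 0.88, adjusted p = 0.00128). In H1093K it was 0.10 (-0.10 to 0.31, adjusted p = 0.737), which did not pass. K165A and WT differed by 0.14 (-0.07 to 0.34), which did not pass either, and K165A lay above H1093K by 0.57 (0.36 to 0.77, adjusted p = 0.00406). Ehmt2 was lower in H1093K than in WT, by -0.43 (-0.63 to -0.22, adjusted p = 0.0185), and this call was lost without WT replicate 1 (adjusted p = 0.144), H1093K replicate 1 (0.132) or H1093K replicate 2 (0.0524). In the arrays labelled deleted, Ehmt2 lay 1.91 above delta (1.71 to 2.12, adjusted p = 2.98e-07), a 3.77-fold difference, and 1.38 above WT (1.18 to 1.59). A second Ehmt2 probe set, too dim to be tested, read 21.8 ± 20.7 in delta, 73.3 ± 45.9 in WT, 134 ± 61.8 in K165A, 86.1 ± 43.0 in H1093K and 204 ± 59.9 in the arrays labelled deleted (SD, n = 2 each). There the H1093K mean lay above those of delta and WT. The level in the arrays labelled deleted goes against that label. Where the probes lie relative to the deleted part of the gene and to the introduced sequence is not given in the sources used here, so the probe sets need not read the introduced form, nor lie inside the deletion.

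**Figure D1:**
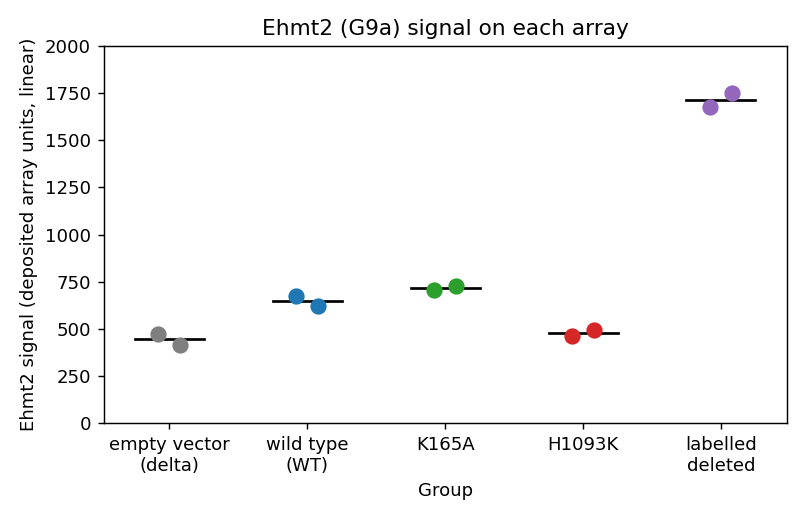
Ehmt2 signal (linear axis, as deposited) on each array by group. Points are arrays and bars are group means of 2 arrays; the arrays labelled deleted have a mean of 1714 against 444 in delta.

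Among the genes that changed most when wild-type G9a was added back to cells without it, Sfrp2, Angpt1 and Igfbp2 rose, and Ppbp, Aldh1a1 and Actg2 fell. Sfrp2, a secreted antagonist of Wnt signalling, rose 32.2-fold, from 298 ± 263 in delta to 8160 ± 935 in WT (SD, n = 2; log2 difference 5.01 ± 0.46 SE, limma adjusted p = 9.27e-05). The size of this rise rested on the delta arrays: it was 63.7-fold without delta replicate 1 and 16.3-fold without delta replicate 2. Angpt1, a ligand of an endothelial receptor kinase, rose from 10.7 ± 11.5 in delta, a level too near background for a fold, to 556 ± 49.7 in WT (SD, n = 2). The growth factor binding protein Igfbp2 rose 10.8-fold. Fbn2, a component of matrix microfibrils, rose 9.98-fold, the transcription factor Osr2 7.06-fold, the signalling protein Bmp4 6.32-fold, and the transcription factors Eomes and Mef2c 5.51-fold and 5.22-fold. Ppbp, a chemokine, fell 10.4-fold, from 3309 ± 268 to 304 ± 31.1 (SD, n = 2; adjusted p = 1.23e-07). Aldh1a1, which makes retinoic acid, fell 8.41-fold, smooth muscle gamma-actin Actg2 8.11-fold, the antiviral enzymes Oas2 and Oas3 7.99-fold and 6.70-fold, and the keratin Krt7 7.43-fold. In all, 1616 of 13575 probe sets passed, 736 higher and 880 lower in WT, for 438 and 579 genes, and 162 and 124 probe sets moved more than 2-fold. With the replicate number as a block, 2813 passed. Without delta replicate 1 the count was 928, without delta replicate 2 it was 881, without WT replicate 1 it was 781, and without WT replicate 2 it was 817. Of the 82 genes named by the rule that passed here, 65 kept the call whichever array was left out, among them every gene named in this paragraph.

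Among the gene lists, the clearest shifts with wild-type G9a were lower interferon-stimulated, cholesterol synthesis and epithelial genes and higher immediate early and bone genes, none of which passed with an estimated correlation (adjusted p = 0.0686 to 0.186). Of 47 interferon-stimulated genes, 15 fell, 4 rose and 28 did not pass (adjusted over the list alone, 18 fell and 4 rose), with Psmb8, a subunit of the immunoproteasome, down 3.07-fold, Trim30a 2.97-fold and H2-K1 2.02-fold. The list was lower by camera (adjusted p = 1.61e-04; adjusted p = 0.124 with an estimated correlation). Of 23 cholesterol synthesis genes, 11 fell, 1 rose and 11 did not pass (over the list alone, 14 fell and 1 rose); camera gave adjusted p = 2.79e-05, and adjusted p = 0.0686 with an estimated correlation. Nsdhl fell 1.75-fold, Msmo1 1.68-fold and Fdps 1.66-fold. Of 11 epithelial markers, 5 fell and 6 did not pass (6 fell over the list alone), including the desmosomal cadherin Dsg2 (3.45-fold) and the keratins Krt18 (3.14-fold) and Krt19 (1.53-fold); the list gave a camera adjusted p of 1.61e-04 (adjusted p = 0.186 with an estimated correlation). Of 30 immediate early genes, which respond within minutes to growth factors and stress, 11 rose, 3 fell and 16 did not pass (over the list alone, 12 rose and 3 fell). Fosb rose 3.34-fold, Jun 2.30-fold, Klf2 1.79-fold and Zfp36 1.65-fold (camera adjusted p = 4.24e-06; adjusted p = 0.147 with an estimated correlation). Among 11 bone and cartilage genes, 5 rose and 6 did not pass (6 rose over the list alone); camera gave adjusted p = 8.41e-05, and adjusted p = 0.119 with an estimated correlation. Besides Bmp4, osteomodulin Omd rose 3.53-fold. Of 56 cell cycle genes, 4 rose and 52 did not pass (3 rose over the list alone); camera gave adjusted p = 0.00503, and adjusted p = 0.209 with an estimated correlation. The mitotic kinesin Kif11 rose 1.36-fold, and the list median was 0.13.

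A further 3 lists passed in WT against delta with less stable calls, also lost with an estimated correlation (adjusted p = 0.147 to 0.207). Of 22 genes of the H3K9 methylation machinery, 5 rose and 17 did not pass (5 rose over the list alone); camera gave adjusted p = 0.0239, and adjusted p = 0.147 with an estimated correlation. Besides Ehmt2, the chromodomain protein Cdyl rose 1.60-fold. The list call was lost without delta replicate 2 (0.0540), without WT replicate 2 (0.0513), or with a gene taken as the mean of its probe sets (0.0910). Of 36 unfolded protein and amino acid stress genes, 5 fell, 2 rose and 29 did not pass (over the list alone, 6 fell and 2 rose); camera gave adjusted p = 0.0483, and adjusted p = 0.151 with an estimated correlation. Asparagine synthetase Asns fell 2.11-fold and the transcription factor Xbp1 fell 1.45-fold. The stress gene call was lost without delta replicate 1 (0.120), WT replicate 2 (0.167), H1093K replicate 1 (0.0514), H1093K replicate 2 (0.0536), deleted replicate 1 (0.0520), deleted replicate 2 (0.0522) or both deleted arrays (0.0517). It was also lost with a pseudocount of 64 (0.0537), the filter at the 60th percentile (0.0568), median centring (0.0539) or only the arrays compared (0.0560). Of 22 inflammatory and NF-kB genes, 8 fell, 2 rose and 12 did not pass (over the list alone, 9 fell and 3 rose); camera gave adjusted p = 0.0474, and adjusted p = 0.207 with an estimated correlation. The chemokine Cxcl5 fell 2.43-fold, Csf1 fell 1.56-fold and Cxcl12 rose 1.92-fold. The replicate block took this list to 0.0691, and it was lost without delta replicate 1 (0.120), WT replicate 1 (0.0549), WT replicate 2 (0.0524), K165A replicate 1 (0.0517), K165A replicate 2 (0.0611), deleted replicate 1 (0.0660), deleted replicate 2 (0.0665) or both deleted arrays (0.0618). A pseudocount of 64 (0.0529), the filter at the 60th percentile (0.0969), only the arrays compared (0.0718) or a gene taken as the mean of its probe sets (0.0507) ended the inflammatory call too.

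The remaining lists did not pass by camera in WT against delta, although single members changed. Imprinted genes went both ways (4 rose, 4 fell and 15 of 23 did not pass, with equal counts over the list alone, adjusted p = 0.524): the growth-restraining genes Plagl1 and Cdkn1c rose 4.32-fold and 1.87-fold, Peg3 rose 4.15-fold and Ndn fell 2.16-fold. Of 49 extracellular matrix genes, 13 rose, 11 fell and 25 did not pass (over the list alone, 15 rose and 12 fell; adjusted p = 0.179), with collagen Col6a3 up 4.62-fold, the protease inhibitor Timp3 up 4.11-fold and Igfbp7 down 2.89-fold. Of 35 p53 targets and cell cycle inhibitors, 11 fell, 2 rose and 22 did not pass (over the list alone, 13 fell and 4 rose; adjusted p = 0.0619), with Ddit4l up 3.99-fold and the kinase Plk2 down 1.72-fold. Smooth muscle genes gave 4 falls among 23 (6 over the list alone, adjusted p = 0.0863), with calponin Cnn1 down 1.88-fold, and adipocyte and lipid genes 4 falls among 15 (6 falls and 2 rises over the list alone, 0.175), with the fatty acid carrier Fabp4 down 2.60-fold. The hypoxia and glycolysis list (2 rose and 1 fell of 25, also over the list alone, adjusted p = 0.935) held both Ndrg1, up 1.82-fold, and the angiogenic factor Vegfa, down 2.53-fold. Neuronal genes (1 rose and 3 fell of 9, also over the list alone, adjusted p = 0.263) included Stmn2, down 3.34-fold, and L1cam, up 2.96-fold. Hox genes (1 rose of 13, 2 over the list alone, adjusted p = 0.493), macrophage and leukocyte markers (2 fell of 6, also over the list alone, 0.359) and endothelial markers (0 of 5, also over the list alone, 0.482) did not pass.

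With the K165A form of G9a, set against delta, Sfrp2, Angpt1 and Fbn2 were again among the genes that rose most, and Ppbp, Actg2 and Oas2 among those that fell most. Sfrp2 rose 29.5-fold, to 7456 ± 570 (SD, n = 2; adjusted p = 1.12e-04; 58.3-fold without delta replicate 1 and 14.9-fold without delta replicate 2). Angpt1 rose to 583 ± 17.0 (SD, n = 2), and Fbn2 rose 7.96-fold, Osr2 6.71-fold, Igfbp2 5.70-fold and Bmp4 5.07-fold. Ppbp fell 12.3-fold, to 255 ± 3.45 (SD, n = 2; adjusted p = 7.41e-08), Actg2 9.92-fold, Oas2 9.13-fold, Moxd1 7.65-fold, Krt7 6.76-fold and the desmosomal protein Pkp2 4.92-fold. limma passed 1529 probe sets, 677 higher and 852 lower, for 399 and 580 genes, and 2678 with the replicate block. Without delta replicate 1 the count was 928, without delta replicate 2 it was 823, without K165A replicate 1 it was 898 and without K165A replicate 2 it was 873. Of the 83 genes named by the rule that passed, 62 kept the call whichever array was left out, among them those named in this paragraph.

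Cholesterol synthesis and epithelial genes were again lower in K165A than in delta by camera, but not with an estimated correlation (adjusted p = 0.0579 and 0.147). Of 23 cholesterol synthesis genes, 11 fell and 12 did not pass (over the list alone, 15 fell and 1 rose); camera gave adjusted p = 5.24e-06, and adjusted p = 0.0579 with an estimated correlation. Msmo1 fell 1.69-fold and Fdps 1.62-fold. Of 11 epithelial markers, 6 fell and 5 did not pass (6 fell over the list alone); camera gave adjusted p = 5.24e-06, and adjusted p = 0.147 with an estimated correlation. Krt18 fell 3.31-fold, Perp 2.20-fold and Krt19 1.90-fold. Among 47 interferon-stimulated genes, 13 fell, 4 rose and 30 did not pass (over the list alone, 15 fell and 5 rose); camera gave adjusted p = 0.0217, and adjusted p = 0.186 with an estimated correlation. The peptide transporter Tap1 and H2-K1 fell 2.22-fold and 2.08-fold, while Ifit3 rose 1.68-fold. The interferon call was lost with the filter at the 60th percentile (0.0568). Among 22 inflammatory genes, 9 fell, 2 rose and 11 did not pass (over the list alone, 10 fell and 2 rose); camera gave adjusted p = 0.00443, and adjusted p = 0.147 with an estimated correlation. Cxcl5 fell 2.46-fold and Cxcl12 rose 1.93-fold. Of 36 unfolded protein and amino acid stress genes, 7 fell and 29 did not pass (7 fell over the list alone); camera gave adjusted p = 0.00916, and adjusted p = 0.132 with an estimated correlation. Asns fell 2.48-fold. Of 23 smooth muscle genes, 6 fell and 17 did not pass (6 fell over the list alone); camera gave adjusted p = 0.0235, and adjusted p = 0.536 with an estimated correlation. Cnn1 fell 1.90-fold. The smooth muscle call was lost without delta replicate 2 (0.113), without K165A replicate 2 (0.0931) or with the filter at the 60th percentile (0.0609).

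Among the lists that were higher in K165A than in delta, 4 of 11 bone and cartilage genes rose and 7 did not pass (5 rose over the list alone); camera gave adjusted p = 8.41e-05, and adjusted p = 0.119 with an estimated correlation. Omd rose 3.63-fold. Of 30 immediate early genes, 8 rose, 3 fell and 19 did not pass (over the list alone, 10 rose and 4 fell); camera gave adjusted p = 0.00643, and adjusted p = 0.278 with an estimated correlation. Fosb rose 2.63-fold, Jun rose 2.45-fold and Noct fell 1.82-fold. Of 22 genes of the H3K9 methylation machinery, 4 rose and 18 did not pass (5 rose over the list alone); camera gave adjusted p = 0.00921, and adjusted p = 0.141 with an estimated correlation. Cdyl rose 1.57-fold. Of 56 cell cycle genes, 4 rose and 52 did not pass (4 rose over the list alone); camera gave adjusted p = 0.00106, and adjusted p = 0.168 with an estimated correlation. Kif11 rose 1.43-fold. Of 13 Hox genes and cofactors, 3 rose, 1 fell and 9 did not pass (over the list alone, 6 rose and 1 fell), and the camera adjusted p was 0.0244 (adjusted p = 0.166 with an estimated correlation), which was lost without K165A replicate 2 (0.0719), with no filter (0.0516) or with the filter at the 60th percentile (0.209).

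**Figure D2:**
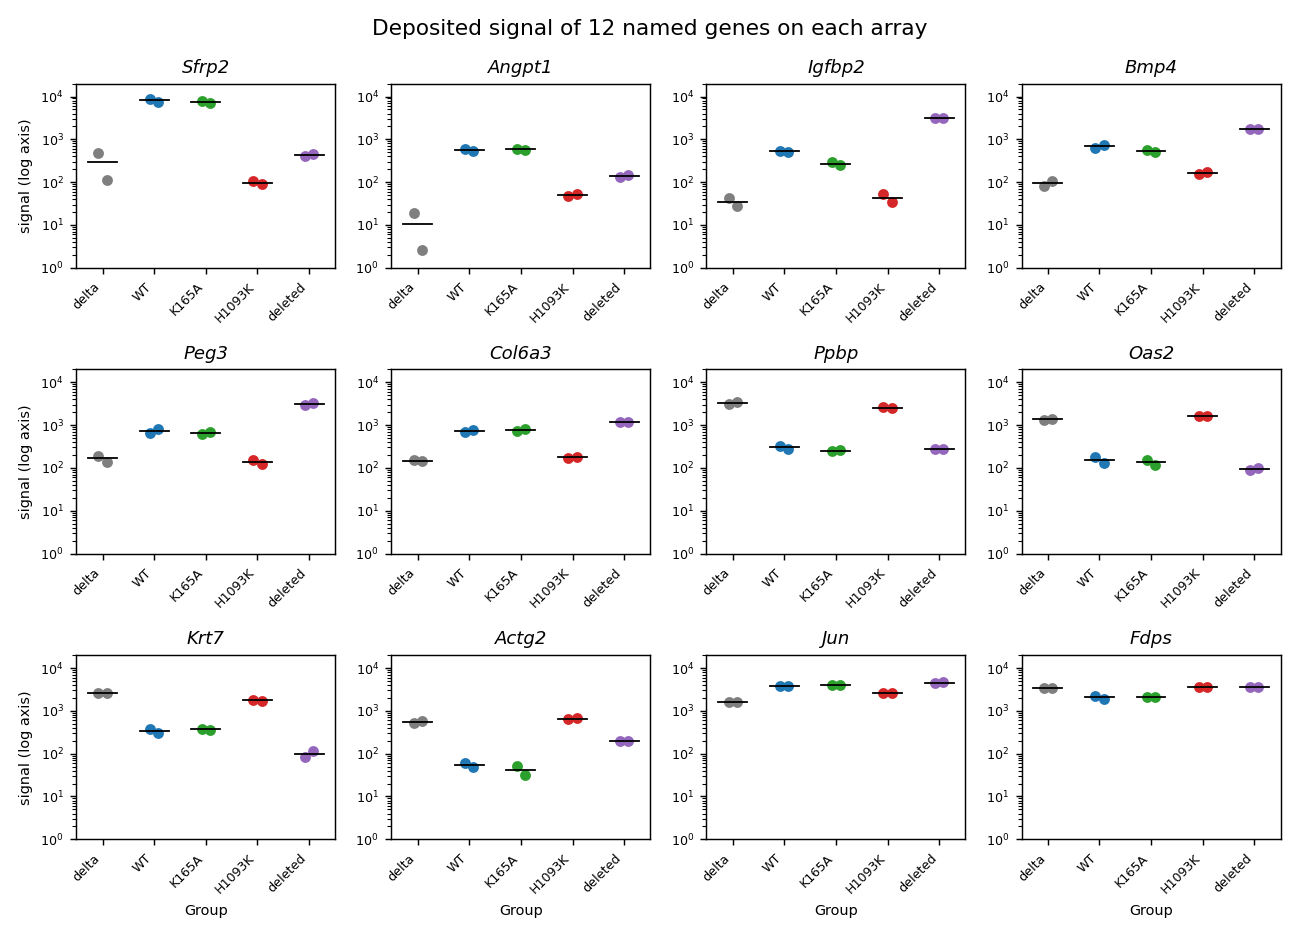
Signal (log axis, as deposited) of 12 genes on each array by group, chosen for display after their values were seen. Points are arrays and bars are group means of 2 arrays; Sfrp2 reads 8160 in WT and 7456 in K165A against 298 in delta and 97.8 in H1093K.

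Set directly against WT, K165A differed in 0 of 13575 probe sets by limma. At an unadjusted p under 0.05 there were 429, fewer than the 678.75 that chance gives, and the smallest adjusted p was 0.436 (0.0625 with the replicate block, which also called 0 and gave 864 at an unadjusted p under 0.05, more than chance gives). The genes with the smallest p did not pass: Id1 and Id2, inhibitors of helix-loop-helix transcription factors, had log2 differences of -0.54 and -0.52 (adjusted p = 0.436 for both), the Notch target Hey1 -1.10 (0.555), the insulin receptor substrate Irs2 -0.74 (0.641) and Igfbp2 -0.93 (0.641), with a signal of 272 ± 34.0 in K165A and 530 ± 22.1 in WT (SD, n = 2 each). Over the 1616 probe sets that passed in WT against delta, the median absolute log2 difference was 0.084 between K165A and WT. It was 0.422 between H1093K and WT and 0.558 between WT and delta. The set was chosen for its difference between WT and delta, so the last value is large by construction. In 1427 of the 1616 probe sets (88.3%) the 95% interval of K165A minus WT lay within 1.5-fold of no difference. It did so in 11243 (82.8%) of all probe sets tested. In the rest the interval reached further.

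By camera with the preset correlation, some whole lists shifted slightly between K165A and WT. In any of them 0 members passed over all probe sets, and camera with an estimated correlation gave adjusted p = 0.119 to 0.476. Across probe sets, K165A minus WT hardly recurred between replicate numbers (r of 0.083). Of the 200 largest differences of the first arrays, 55.5% had the same sign in the second, and 54.5% the other way round. Immediate early genes lay lower in K165A, with a median of -0.14 over 30 genes, and 2 fell over the list alone (camera adjusted p = 2.61e-07; adjusted p = 0.141 with an estimated correlation). Its members of smallest p were Noct (-0.35), the MAP kinase phosphatase Dusp6 (-0.43), Ier5 (-0.25) and Hbegf (-0.27). Interferon-stimulated genes lay higher, with a median of 0.09 over 47 genes (camera adjusted p = 3.62e-05; adjusted p = 0.119 with an estimated correlation), as with Stat2 (0.31) and Gbp2 (0.24). Hox genes lay higher, with a median of 0.17 over 13 (camera adjusted p = 7.03e-04; adjusted p = 0.124 with an estimated correlation), as with Hoxd8 (0.51) and Hoxa5 (0.45), and lost the call without K165A replicate 2 (0.118). In the interferon, Hox and epithelial lists, 0 members passed over the list alone by limma either. Epithelial markers lay lower, with a median of -0.12 over 11 (camera adjusted p = 0.0474; adjusted p = 0.476 with an estimated correlation). The replicate block took that list to 0.0674, and it was lost without delta replicate 1 (0.0598), delta replicate 2 (0.0541), either WT replicate (0.127 each), K165A replicate 2 (0.906), deleted replicate 1 (0.0793), deleted replicate 2 (0.0778) or both deleted arrays (0.0791). The epithelial call was also lost with no filter (0.782), the filter at the 60th percentile (0.101), a pseudocount of 64 (0.0577), median centring (0.0586) or only the arrays compared (0.0788).

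The H1093K mutant changed far fewer genes against delta. Aspn, a small matrix proteoglycan, rose 2.15-fold, from 353 ± 27.1 to 775 ± 29.1 (SD, n = 2; limma adjusted p = 0.00149), and Jun rose 1.63-fold. Mef2c rose 1.98-fold and Timp3 1.81-fold. Nrarp, a regulator of Notch signalling, fell 2.81-fold, from 780 ± 81.6 to 266 ± 7.92 (SD, n = 2), the Hedgehog transcription factor Gli2 fell 2.29-fold, the phosphodiesterase Pde4b 2.20-fold, and Id4 and Id1 1.87-fold and 1.76-fold. In all, 111 probe sets passed, 61 higher and 50 lower, for 39 and 36 genes, and 471 with the replicate block. This count rested on single arrays: it was 36 without delta replicate 1, 17 without delta replicate 2, 14 without H1093K replicate 1, 7 without H1093K replicate 2, 48 without WT replicate 1 or WT replicate 2, and 66 without deleted replicate 1 or deleted replicate 2. With only the 4 arrays compared it was 0, with 1398 at an unadjusted p under 0.05. Of the 32 genes named by the rule that passed, 2 (Aspn and Jun) kept the call whichever array was left out.

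In H1093K against delta, list medians moved while few members passed. Of 56 cell cycle genes, 1 (the cyclin Ccnb2, 1.36-fold) rose and 55 did not pass (3 rose over the list alone); camera gave adjusted p = 1.99e-06, and adjusted p = 0.125 with an estimated correlation. The list median was 0.14. Of 11 bone and cartilage genes, 0 passed over all probe sets and 3 rose over the list alone, with a median of 0.36 (camera adjusted p = 0.00177; adjusted p = 0.143 with an estimated correlation). Of 23 cholesterol synthesis genes, 0 passed over all probe sets and 4 rose over the list alone, with a median of 0.13 (camera adjusted p = 0.00443; adjusted p = 0.125 with an estimated correlation). Of 47 interferon-stimulated genes, 2 rose (Ifit3 and Ifit2, 1.41-fold each) and 45 did not pass (over the list alone, 2 rose and 1 fell; camera adjusted p = 0.00555, adjusted p = 0.147 with an estimated correlation), a call lost without delta replicate 1 (0.0915). Of 11 epithelial markers, 0 passed over all probe sets and 3 fell over the list alone (camera adjusted p = 0.0217; adjusted p = 0.392 with an estimated correlation), a call lost without delta replicate 1 (0.194), without H1093K replicate 2 (0.210) or with no filter (0.215). Of 35 p53 targets and cell cycle inhibitors, 2 fell (Ccng1 1.48-fold and Mdm2 1.34-fold), 1 rose (Gadd45a, 1.64-fold) and 32 did not pass (over the list alone, 6 fell and 1 rose; camera adjusted p = 0.0239, adjusted p = 0.147 with an estimated correlation), a call lost without delta replicate 1 (0.140) or H1093K replicate 2 (0.0584).

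Set against WT, the H1093K arrays had lower Sfrp2, Fbn2 and Igfbp2 and higher Asb5, Oas2 and Actg2. Sfrp2 was 71.7-fold lower, at 97.8 ± 8.44 against 8160 ± 935 (SD, n = 2; limma adjusted p = 3.47e-05), Fbn2 10.2-fold lower, Igfbp2 9.38-fold, Angpt1 8.66-fold and Peg3 4.92-fold. Asb5 was 11.1-fold higher, Oas2 and Actg2 9.48-fold each, Aldh1a1 9.16-fold, Ppbp 8.08-fold and Krt7 5.07-fold. Of 47 interferon-stimulated genes, 23 were higher and 24 did not pass (over the list alone, 25 higher and 1 lower), including the antiviral gene Rsad2 (2.16-fold) and the immunoproteasome subunit Psmb9 (2.24-fold); camera gave an adjusted p of 2.40e-09 (adjusted p = 0.0559 with an estimated correlation). Of 23 cholesterol synthesis genes, 12 were higher and 11 did not pass (over the list alone, 15 higher and 1 lower); camera gave adjusted p = 2.86e-09, and adjusted p = 0.0557 with an estimated correlation. Msmo1 was 2.01-fold higher, Fdps 1.77-fold and Cyp51 1.56-fold. Of 30 immediate early genes, 12 were lower and 18 did not pass (16 lower over the list alone); camera gave adjusted p = 4.32e-10, and adjusted p = 0.119 with an estimated correlation. Fosb was 3.07-fold lower, Klf2 1.97-fold and Zfp36 1.96-fold. Of 11 epithelial markers, 3 were higher and 8 did not pass (4 over the list alone; camera adjusted p = 0.00296, adjusted p = 0.261 with an estimated correlation), and of 11 bone and cartilage genes, 3 were lower and 8 did not pass (3 over the list alone; camera adjusted p = 0.00643, adjusted p = 0.147 with an estimated correlation). The H3K9 methylation machinery (3 of 22 lower, 5 over the list alone) gave a camera adjusted p of 0.0269 (adjusted p = 0.147 with an estimated correlation), lost without WT replicate 2 (0.0699) or H1093K replicate 2 (0.0720).

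The count of probe sets that differed between H1093K and WT was 1090, 550 higher and 540 lower in H1093K, for 353 and 334 genes, and 1945 with the replicate block. It was 563 without WT replicate 1, 644 without WT replicate 2, 548 without H1093K replicate 1 and 631 without H1093K replicate 2. The genes named for this comparison by their fold kept their calls whichever array was left out.

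Against H1093K, the K165A arrays had higher Sfrp2, Angpt1 and Fbn2 and lower Actg2, Oas2 and Ppbp. The H1093K arrays serve this comparison and the one with WT. Sfrp2 was 65.6-fold higher in K165A (log2 difference 6.04 ± 0.46 SE, n = 2, limma adjusted p = 3.77e-05), Angpt1 9.09-fold and Fbn2 8.14-fold, while Actg2 was 11.6-fold lower, Oas2 10.8-fold, Ppbp 9.53-fold and the metalloprotease Tll1 5.08-fold. Cholesterol synthesis genes were lower in K165A in 11 of 23 and 12 did not pass (over the list alone, 14 lower and 1 higher; camera adjusted p = 4.32e-10, adjusted p = 0.0557 with an estimated correlation), with Msmo1 2.02-fold lower. Interferon-stimulated genes were lower in 18 of 47 and 29 did not pass (over the list alone, 23 lower and 2 higher; camera adjusted p = 4.24e-06, adjusted p = 0.0982 with an estimated correlation), with Psmb9 2.14-fold lower. Immediate early genes were higher in 8 and lower in 2 of 30 (over the list alone, 14 and 2; camera adjusted p = 2.79e-05, adjusted p = 0.150 with an estimated correlation), with Fosb 2.43-fold higher. Epithelial markers were lower in 5 of 11 (6 over the list alone; camera adjusted p = 3.73e-05, adjusted p = 0.166 with an estimated correlation), and bone and cartilage genes higher in 2 of 11 (3 over the list alone; 0.00694, adjusted p = 0.147 with an estimated correlation). The H3K9 methylation machinery was higher in 3 of 22 (3 over the list alone; 0.00943, adjusted p = 0.141 with an estimated correlation). Unfolded protein and amino acid stress genes were lower in 4 and higher in 1 of 36 (over the list alone, 10 and 2; 0.0248, adjusted p = 0.147 with an estimated correlation), lost without K165A replicate 2 (0.0851). Inflammatory genes were lower in 5 and higher in 2 of 22 (over the list alone, 7 and 2; 0.00891, adjusted p = 0.147 with an estimated correlation), also lost without K165A replicate 2 (0.0582). In all, 1007 probe sets passed, 479 higher and 528 lower, for 282 and 341 genes, and 1852 with the replicate block. The count was 571 without K165A replicate 1, 542 without H1093K replicate 1 and 567 without H1093K replicate 2.

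**Figure D3:**
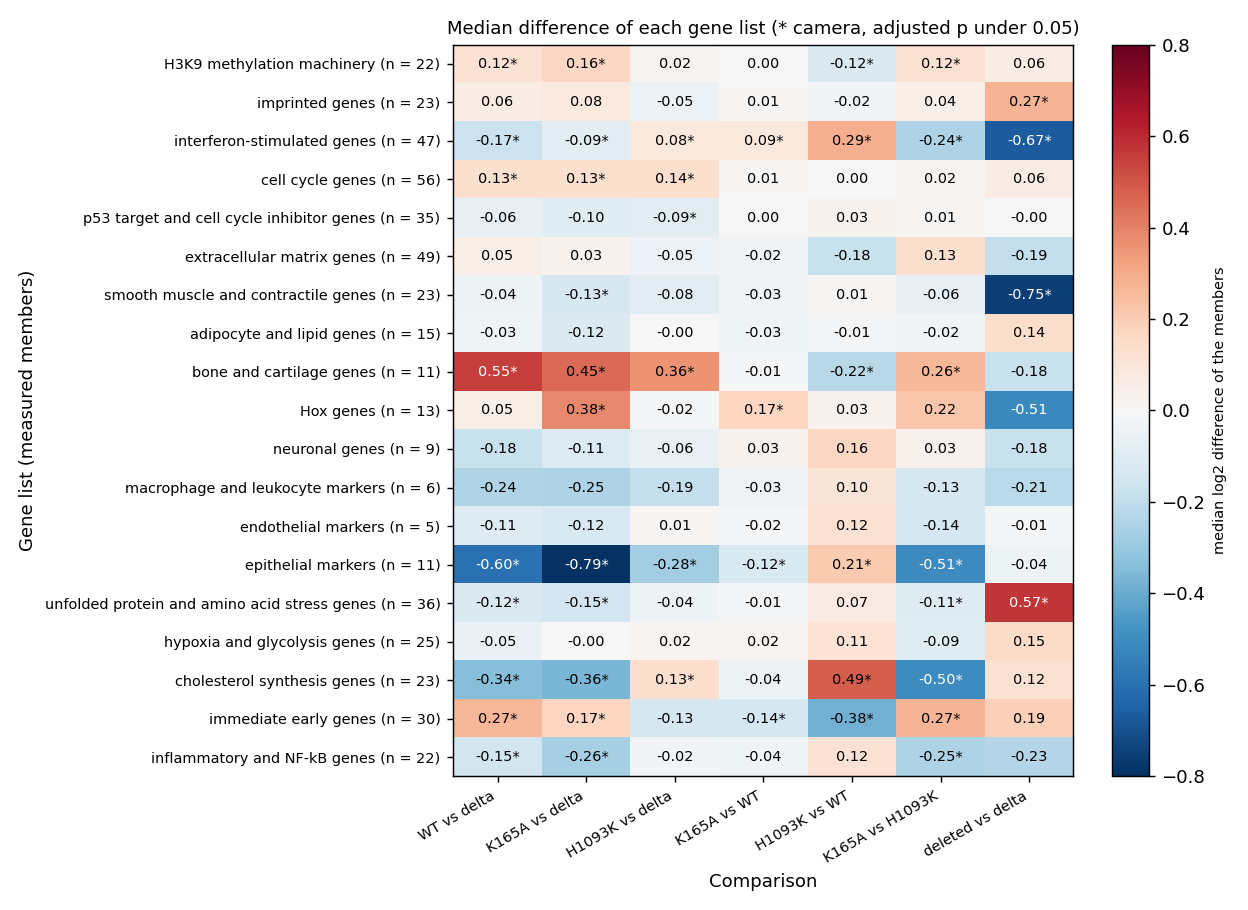
Median log2 difference of the measured members of each tested gene list (vertical axis) in each of the 7 comparisons (horizontal axis), by colour and value. Asterisks mark a camera adjusted p under 0.05 with the preset correlation, as for the 23 cholesterol synthesis genes with a median of -0.34 in WT against delta; none of the marked pairs passed with an estimated correlation.

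Over the 1616 probe sets that responded to wild-type G9a, the K165A form moved genes such as Sfrp2, Bmp4, Oas2 and Krt7 by nearly the WT amount. The H1093K form followed the WT response little over the set. Single genes went the other way: in H1093K, mean Sfrp2 lay below delta and mean Asb5 above it, opposite to WT. The slope of K165A minus delta on WT minus delta was 0.971 (0.950 and 0.973 by replicate number), with 1614 probe sets of the same sign, 1209 also past the threshold for K165A and 0 differing between K165A and WT. For H1093K the slope was 0.177 (0.164 and 0.198), with 1232 (76.2%) of the same sign, 70 also past the threshold and 798 (49.4%) differing between H1093K and WT. Leaving out delta replicate 1 took this slope to 0.237, and leaving out WT replicate 1 or WT replicate 2 to 0.150 and 0.152. The delta arrays enter both differences. In 100 simulated data sets in which the mutant equalled delta, the mean slope was 0.0563 (highest 0.0665). There 62.6% had the same sign, and the correlation across all probe sets was 0.197. The simulated noise was independent between probe sets and arrays, so the highest slope is no bound for the real arrays. The observed correlations were 0.919 for K165A and 0.411 for H1093K. The covariances were 0.125 and 0.0315 against 0.0125 in the simulations, which leaves 0.112 and 0.0190 beyond what independent noise gives. Shared calls with WT numbered 536 higher and 673 lower for K165A, where independent lists of these sizes would share 36.7 and 55.2, and 39 higher and 31 lower for H1093K, against 3.31 and 3.24. With 2 delta arrays the controls could not be split with 2 arrays in each part, and part of the excess may come from sharing them. The arrays labelled deleted, set against the same delta arrays, had a slope of 0.726, with 72.9% of the same sign. There 813 probe sets also passed with the WT sign and 222 with the opposite sign. What those cells carried is not known, so this slope cannot tell a response to G9a from a deviation of the delta arrays.

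**Figure D4:**
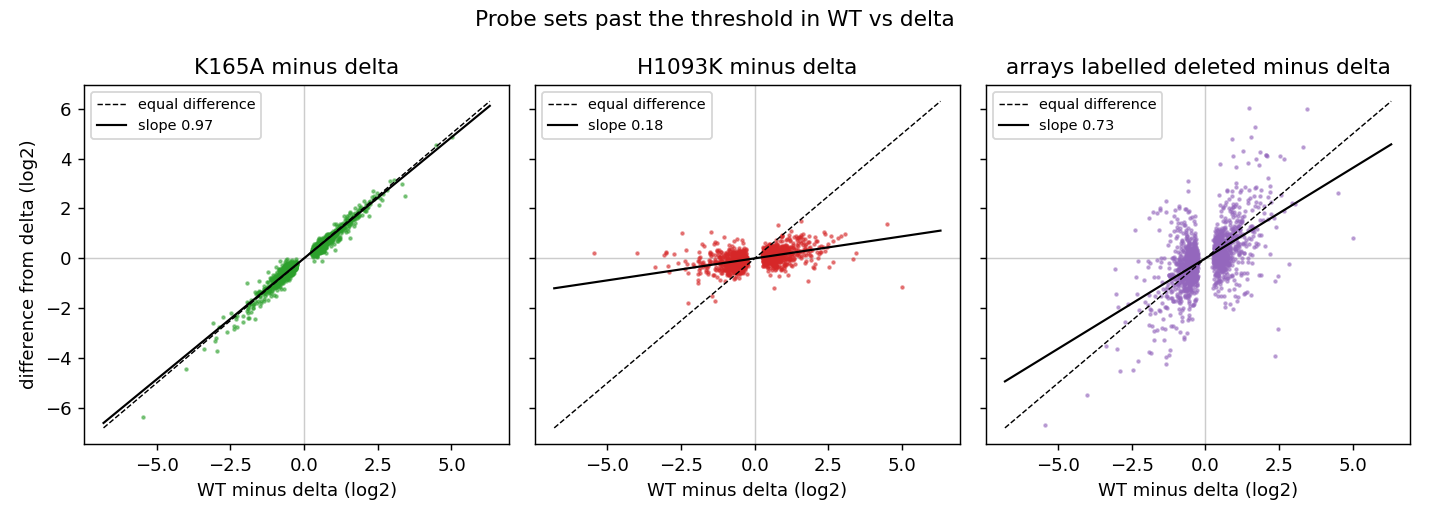
Log2 differences of K165A, of H1093K and of the arrays labelled deleted from delta (vertical axes) against those of WT from delta (horizontal axes). Each point is 1 of the 1616 probe sets past the threshold in WT against delta. Solid lines show the fitted slopes, 0.971 for K165A, 0.177 for H1093K and 0.726 for the arrays labelled deleted. Dashed lines mark equal differences. All differences use the same 2 delta arrays.

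The arrays labelled deleted differed from delta at more probe sets than any other group did, with higher Igfbp2, Dlk1 and Igf2 and lower Krt7, Asb5 and Ppbp. Since Ehmt2 was highest there, a direction from this comparison cannot be read as that of losing G9a. Igfbp2 was 62.9-fold above delta (3148 ± 53.6 against 34.8 ± 9.96, SD, n = 2; limma adjusted p = 2.24e-08), the imprinted gene Dlk1 45.2-fold, Igfbp6 37.8-fold, the growth factor Igf2 21.9-fold (40.3-fold without delta replicate 1 and 11.9-fold without delta replicate 2), the matrix protein Postn 20.6-fold and Timp3 17.7-fold. Asb5 read 9.85 ± 1.75, near background, against 556 ± 58.7 in delta (SD, n = 2). Krt7 was 23.2-fold lower, Serpinb1a 15.4-fold (82.4 ± 0.699 against 1502 ± 31.0, SD, n = 2; adjusted p = 1.02e-08), the gap junction gene Gjb2 12.8-fold and Ppbp 11.3-fold. In all, 4475 probe sets passed, 2115 higher and 2360 lower, for 1292 and 1463 genes, and 435 and 453 moved more than 2-fold. Of the 85 genes named by the rule that passed, 82 kept the call whichever array was left out.

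Of 23 imprinted genes, 11 were higher than delta in the arrays labelled deleted, 3 lower and 9 did not pass (11 and 3 over the list alone); camera gave adjusted p = 0.00503, and adjusted p = 0.147 with an estimated correlation. Peg3 was 17.5-fold and Meg3 12.3-fold higher. The call of imprinted genes was lost with the filter at the 60th percentile (0.0529). Of 36 unfolded protein and amino acid stress genes, 21 were higher, 3 lower and 12 did not pass (over the list alone, 21 and 4); camera gave adjusted p = 4.24e-06, and adjusted p = 0.0559 with an estimated correlation. Asns was 3.28-fold and the serine synthesis enzyme Phgdh 3.23-fold higher. Of 47 interferon-stimulated genes, 32 were lower, 2 higher and 13 did not pass (over the list alone, 34 and 3); camera gave adjusted p = 4.32e-10, and adjusted p = 0.0559 with an estimated correlation. Oas2 was 12.4-fold, Iigp1 3.41-fold and Ifit3 2.82-fold lower. Of 23 smooth muscle genes, 17 were lower and 6 did not pass (18 over the list alone); camera gave adjusted p = 3.19e-08, and adjusted p = 0.166 with an estimated correlation. The integrin Itga7 was 5.21-fold, Cnn1 4.10-fold and the myosin light chain Myl9 3.07-fold lower. Other lists did not pass by camera but held members that went both ways: epithelial markers (4 higher and 2 lower of 11, also over the list alone, adjusted p = 0.443) had Krt8 11.3-fold higher beside the lower Krt7, and immediate early genes (10 higher and 8 lower of 30, also over the list alone, 0.311) had Egr2 6.50-fold higher and Noct 3.80-fold lower. Extracellular matrix genes, of which 17 were higher and 20 lower among 49 (18 and 23 over the list alone, adjusted p = 0.975), had a median of -0.19, a mean of 0.40 and a downward camera direction. The median of the epithelial markers (-0.04) also differed in sign from their mean (0.33) and from the upward camera direction, and bone and cartilage genes (2 higher and 5 lower of 11, also over the list alone, 0.561) had a median of -0.18, a mean just above 0 and a downward camera direction.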

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

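Chosen only after the results they measure had been seen were the tests of an exchange of arrays, of an intact G9a gene, of a labelling difference, of a lower G9a transcript level, of lost catalytic activity, of a culture difference of the delta arrays and of slopes within groups; the tests of array brightness and of the shared delta arrays were set beforehand.

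A control probe set for the mouse B1 repeat, which no comparison used, read 7003 ± 437 in the arrays labelled deleted and 2358 ± 199 in delta (SD, n = 2 each), a ratio of 2.97, with both arrays labelled deleted above both delta arrays. It read 2992 ± 194 in WT and 2942 ± 67.5 in K165A, where both arrays of each group also lay above both delta arrays, and 2225 ± 187 in H1093K (SD, n = 2 each).

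Ehmt2 was highest in the arrays whose title says deleted, with a signal of 1714 against 444 in delta. If the cells titled deleted lacked added G9a, an exchange with the WT arrays would leave the arrays labelled WT without it. Ehmt2 in the arrays labelled WT lay 0.53 above delta (95% interval 0.33 to 0.74, log2), which goes against that reading. What those cells carried and what the probe set reads are not known, so an exchange cannot be excluded. Array brightness is argued against, since the smallest difference of the arrays labelled deleted from delta over 4 scalings was 1.91, with interval bounds no lower than 1.69. Cells that still carry an intact G9a gene stay a candidate explanation. Of 1007 probe sets that differed between K165A and H1093K, deleted minus delta had the same sign in 74.0% (73.1% and 73.6% by replicate number). In deleted against delta, 555 of the 1007 passed with that sign and 148 with the opposite sign. The 2 comparisons share no array, but the delta and H1093K arrays were close to each other (mean r of 0.982). Anything that sets both groups apart from the others would raise this share, so it cannot tell an intact gene from another origin. Another fibroblast line or origin stays open too, since 12 of 13 Hox genes and cofactors (92.3%) differed between the arrays labelled deleted and delta. In that comparison 4475 of all 13575 probe sets differed. A probe outside the deleted part of the gene would check nothing.

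The WT and K165A arrays stood apart from the delta and H1093K arrays. A labelling difference confined to the first arrays is argued against, since 96.5% of the 200 largest WT minus delta differences of the first arrays had the same sign in the second. A lower G9a transcript level in the H1093K cells is a candidate explanation, with Ehmt2 in H1093K minus WT at -0.43 (95% interval -0.63 to -0.22) by the probe set tested, although the second, dimmer one read 86.1 ± 43.0 in H1093K and 73.3 ± 45.9 in WT (SD, n = 2 each). Loss of catalytic activity, which the design names for this mutant, cannot be told apart from it here. That would need H1093K Ehmt2 above the delta level, and the difference was 0.10 (-0.10 to 0.31) by the probe set tested. By the dimmer one, which was not tested, both H1093K arrays lay above both delta arrays (mean 86.1 against 21.8), so the 2 probe sets differ on this point. Whether the probe sets read the introduced transcript is not known, so a low Ehmt2 signal need not mean a low level of the mutant protein.

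A small part of the WT response appeared in the H1093K arrays, with a slope of 0.177 against 0.0563 in simulations of an unchanged group with independent noise. Gene lists did not all follow WT. By camera against delta, cholesterol synthesis genes were lower in WT but higher in H1093K, while bone and cartilage genes and cell cycle genes were higher in both. None of these list calls passed with an estimated correlation. With no array in common between the 2 axes, the slope over the 200 largest differences was 0.132 in one direction and 0.0857 in the other, and 71.5% and 70.5% had the same sign. The smaller slope missed the bound of 0.1 set beforehand, so this test leaves open whether the shared delta arrays are the whole cause. For scale, 6 slopes of one array minus the other of its group lay between -0.0549 and 0.0329, at most 0.0549 in size. These hold no delta array on the vertical axis. They show the spread within groups only and cannot argue against a deviation common to both delta arrays. A culture difference of the delta arrays alone stays open beside a weak response and may produce it: 68 probe sets passed in WT, K165A and H1093K against delta with one sign, and deleted minus delta had that sign in 77.9% of them. That comparison uses the delta arrays as well, and simulations with no difference at all gave 98.8% for sets chosen in this way, so the share decides nothing.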

How the results depend on the processing

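Leaving out the arrays labelled deleted and the slope of mutant minus deleted on WT minus delta were chosen after seeing the data; the other settings were planned. No setting reversed a named gene: of 432 pairs of gene and comparison, 318 kept their side of the threshold in every setting that tested them. The other 114 lost a call in at least 1. Not every setting tested every pair: the filter at the 60th percentile tested 323 of the 432 and the pseudocount of 1 tested 425. Of 48 list calls, 33 kept their side in every setting that tested them except the estimated correlation, which left 0, and 15 lost it in at least 1 other setting. The replicate block ended 2 list calls and no gene call, and raised the counts to 2813 (WT against delta), 2678 (K165A against delta), 471 (H1093K against delta), 1945 (H1093K against WT) and 1852 (K165A against H1093K). Requiring 1.5-fold left 747, 734, 62, 608 and 576 in that order and 2235 for the arrays labelled deleted against delta, by construction. With the arrays labelled deleted as the control, 4398 (WT), 4295 (K165A) and 4528 (H1093K) passed. Using only the arrays compared, with fewer residual degrees of freedom, gave 805 for K165A against delta, 0 for H1093K against delta (1398 at an unadjusted p under 0.05 by limma) and 663 for K165A against H1093K. H1093K against delta gave 60 with no filter, 53 with no intensity trend and 65 without the arrays labelled deleted; the cause was not tested. K165A against WT stayed at 0 by limma in all settings, with 283 to 864 probe sets at an unadjusted p under 0.05 and a smallest adjusted p of 0.0625 to 0.999. No scaling between arrays moved the share of higher calls by over 10 percentage points or the median of all genes by over 0.1. Leaving out 1 array at a time, with the lone array assumed to vary like the other groups, gave 781 to 1566 for WT against delta, 823 to 1351 for K165A against delta, 7 to 88 for H1093K against delta, 548 to 1034 for H1093K against WT, 542 to 948 for K165A against H1093K and 3265 to 4736 for any difference. The K165A slope of 0.971 ranged over 0.945 to 0.995 in this way, was 1.01 on the 200 smallest p, and 0.245 as mutant minus deleted on WT minus delta. The H1093K slope of 0.177 ranged over 0.150 to 0.237, was 0.201 with the filter at the 60th percentile and 0.139 on the 200 smallest p. Against the arrays labelled deleted on both axes it was 0.820, and as mutant minus deleted on WT minus delta it reversed to -0.549; these 2 follow from the change of control, since the arrays labelled deleted differ from every other group. Signal near background limits what can be seen of dim genes, most of which the filter leaves out.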

Other observations

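The comparison of correlations between arrays was chosen after the values were seen, and the Hox counts come from planned tests. Hox genes and their cofactors differed most in the arrays labelled deleted, where 5 of 13 were higher than delta, 7 lower and 1 did not pass, also when adjusted over the list alone. Hoxa9 was 4.35-fold lower, Hoxa11 3.10-fold and Hoxd13 2.41-fold, while the cofactor Meis2 was 4.29-fold higher. The list as a whole did not pass by camera (adjusted p = 0.349), with members going both ways. In WT against delta 1 of 13 passed (2 over the list alone), and in K165A against delta 4 of 13 passed (7 over the list alone). Of all 13575 probe sets, 4475 passed in the arrays labelled deleted against delta, 1616 in WT and 1529 in K165A, so more members of any list would pass in the first. Whether the Hox list exceeded that share was not tested.

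Each array of the delta, WT, K165A and H1093K groups except WT replicate 1 and H1093K replicate 2 correlated more closely with a same-numbered array of another group than with the other array of its own group. K165A replicate 2 and WT replicate 2 had r of 0.993 across probe sets, against 0.984 between the 2 K165A arrays. Delta replicate 1 and H1093K replicate 1 had 0.987, against 0.984 between the 2 delta arrays. The hybridisation controls moved with the replicate number in some groups. The bioB control read 285 in delta replicate 1 and 568 in delta replicate 2. It read 231 and 527 in H1093K, 271 and 501 in the arrays labelled deleted, and 377 and 473 in K165A. In WT it fell from 559 to 489. Among the first arrays it was thus lower in delta, H1093K and deleted than in WT and K165A. This control therefore does not show the assumed pairing in every group.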
